A study of Mus musculus with 24 samples.

How the data were processed

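Per the labels, glands were snap frozen and polyA RNA was sequenced. The aligner, the counting tool and the settings are not given in the sources used here, and the builds GRCm38 and mm10 come from the submitters' processing notes. The table the authors deposited holds 32544 gene symbols and 48 columns, 2 for each of 24 samples, named after the first and second read files.

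The deposited values are log10 of CPM plus 1, read from the values themselves, since each column sums to 1000000 CPM after that transform is undone. The tests had been written for log2 CPM, so the values were converted to log2(CPM + 1) and the tests kept. Whole reads were recovered in 100% of values of every column within a tolerance of 0.05, and the total reads per column follow from that. The 2 columns of 23 samples differed in reads by at most 0.45%, and between the columns of 22 of 24 samples the values of a gene differed by no more than counting noise (chi-square per gene at or below 1). Replicate mice gave 11.8 to 210.6 on that measure. The 2 columns were therefore averaged in CPM and counted as 1 replicate. Symbols that a spreadsheet had turned into dates, 27 in all, were kept in the totals and named nowhere.

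Genes were tested with limma (lmFit, contrasts.fit, eBayes with a variance trend) in a fit of 24 samples and 8 group means with 16 residual degrees of freedom, 2-sided, with Benjamini-Hochberg adjustment within each of 17 comparisons and a threshold of 0.05. The 16162 genes with CPM above 1 in at least 3 samples were tested. The comparisons, tests, lists, rule for named genes and most alternatives were chosen before the data were examined.

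For each comparison up to 10 genes with the largest increases and 10 with the largest decreases were eligible to be named, among genes past the threshold with no overlap between groups and a mean log2 CPM of at least 2 in the higher group. Unnamed gene models, immunoglobulin and T cell receptor segments and pseudogenes were left out of that rule. Up to 4 members of each described list with the smallest adjusted p, and members that went the other way, were eligible too, as was a fixed set of mitochondrial, milk and stress genes.

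The 54 lists, written from general knowledge, cover milk synthesis, involution, mitochondria, other organelles, tissue processes, technical markers and cell types. A list with 3 or more measured genes was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera asks whether the genes of a list moved more one way than the other genes did. Gene positions are from GENCODE release 21 for mouse (GRCm38), matched by symbol, with 15657 tested symbols found once.

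Shares of counts were compared by permuting genotype within stage, 100000 resamples, and by an exact permutation within a stage, where 3 against 3 gives no p below 0.1. The F numbers of the titles did not pair mice across groups, so they served in a block setting alone. On data simulated for non-lactating glands (16029 genes) limma called 45% of 100 genes changed 2-fold and 89% of 100 changed 4-fold. Of 182 calls 48 were false (26.4%), against 2 of 57 with the compared groups alone and 4 of 121 with limma voom. For day 8 (16307 genes) 6 of 121 calls were false. The median SD within a group was 0.27 in C57 and 0.4 in NZB non-lactating glands. The work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.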

Results

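The series measured polyadenylated RNA in inguinal mammary glands of mice of 2 genotypes on a BL/6 background, named C57 and NZB. These names are used for strains that carry the mitochondrial DNA of C57 or NZB mice, and the title of the series asks how organelles respond to the stress of lactation. Glands were taken from non-lactating mice and on lactation days 8, 14 and 21, with 3 mice in each of the 8 groups and 24 samples in all. Depth is given in units of 1000000 reads assigned to genes, averaged over the 2 columns of a sample. Non-lactating glands had 7.03 to 15.88 (C57) and 9.92 to 13.45 (NZB). Lactating groups had 20.02 to 22.12 (C57) and 21.40 to 24.25 (NZB) on day 8, 18.54 to 21.33 and 20.57 to 23.33 on day 14, and 17.55 to 21.11 and 14.81 to 18.87 on day 21. In C57 non-lactating mouse 2 the first column held 2.17 and the second 11.89. C57 non-lactating mouse 3 is named NZB in its genotype tag and C57 in its title. It held 3591.28 CPM (counts per 1000000) of Gm29216, a nuclear copy of mt-Co1 that stood at 0 CPM in all NZB glands, and it was kept as C57.

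Milk protein transcripts filled the lactating glands. In C57 the 19 measured milk protein genes held 0.47% ± 0.01 (SD, n = 3) of all counts in non-lactating glands, 74.35% ± 2.73 on day 8, 70.87% ± 5.94 on day 14 and 70.79% ± 7.81 on day 21. NZB glands held 1.48% ± 0.49 before lactation, 74.13% ± 1.68 on day 8 and 72.16% ± 3.53 on day 14, and then 24.66% ± 6.23 on day 21. On day 21 the genotypes differed by −46.14 percentage points (NZB less C57), and the exact permutation p was 0.1, the smallest that 3 against 3 allows. Over the 3 lactation days the mean was 56.98% in NZB and 72.0% in C57, a difference of −15.02 points (2-sided permutation p = 0.06). Without day 21 the difference was 0.53 points (permutation p = 0.8003). Leaving out 1 mouse gave −17.32 to −10.15 points (6 with permutation p under 0.05), but unbalances pooled days.

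**Figure D1:**
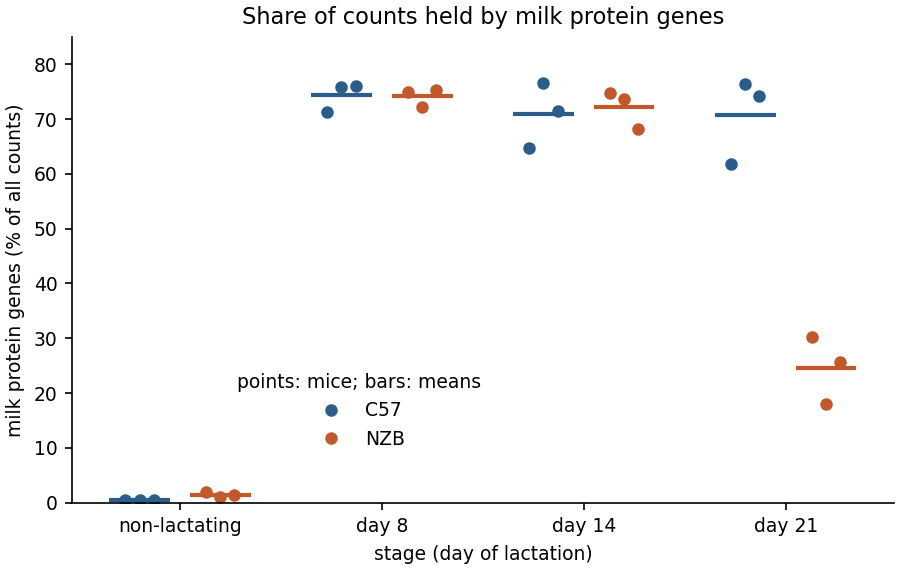
Share of all counts held by the 19 milk protein genes (percent) in each of 24 glands, by stage and genotype, with points for mice and bars for group means. The 3 NZB glands of lactation day 21 held 17.97 to 30.3%, below all other lactating glands.

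Because these few genes took most of the counts in C57 on all 3 days and in NZB on days 8 and 14, the CPM of most other genes was lower there. Gene counts are therefore given on the deposited scale and then on the non-milk scale, where the milk protein genes were left out and the remaining CPM rescaled to the same total. Folds of single genes are log2 on the non-milk scale, or the deposited scale for milk protein genes. Errors are limma standard errors pooled over all 24 samples, which can understate the spread of NZB non-lactating glands. Putting the non-milk folds first was chosen after the data were seen.

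Lactation day 8 was compared with the non-lactating state in C57 to ask which genes change when the gland makes milk. On the deposited scale Csn2 rose by 8.06 (SE 0.38), Csn1s2a, another casein, by 8.26 (SE 0.34), Wap, the whey acidic protein, by 8.00 (SE 0.37) and Glycam1, a mucin-like milk protein, by 8.47 (SE 0.43). Lalba, which makes the galactosyltransferase B4galt1 produce lactose, rose by 6.94 (SE 0.26), and B4galt1 itself by 4.36 (SE 0.27). Slc34a2, a phosphate transporter, rose by 9.85 (SE 0.38), Fabp3, a fatty acid carrier, by 9.81 (SE 0.30), Atp2b2, the pump that moves calcium into milk, by 8.85 (SE 0.39) and Btn1a1, a coat protein of the milk fat globule, by 6.83 (SE 0.29). The fat cell genes Dgat2 (−5.84, SE 0.55), Plin1 (−5.11, SE 0.43), Lep (−4.69, SE 0.43) and Adipoq (−4.66, SE 0.51) fell. So did Foxa1 (−6.19, SE 0.65) and the progesterone receptor Pgr (−5.53, SE 0.63) of hormone-sensing epithelium, and Npr3, Sncg, Mmd and Serpina3n (−5.84, −5.84, −5.88 and −5.68).

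Among milk protein genes, 18 of 19 measured genes rose and 1 fell (18 and 1 adjusted over the list alone). The median was 6.94 (camera adjusted p = 2.1e-94, 5.2e-07 with an estimated correlation). The member that fell was Wfdc21 (−2.79, SE 0.34). Among genes of calcium and ion transport, 10 of 15 measured genes rose and 3 fell (10 and 3 adjusted over the list alone). The median was 2.42 (camera adjusted p = 1.1e-08, 0.003 with an estimated correlation). Atp2c2 (5.15, SE 0.26), a calcium pump of the secretory pathway, and the zinc carrier Slc30a2 (5.02, SE 0.25) were among those that rose. For lactose synthesis and glucose transport, 5 of 13 measured genes rose and 1 fell (5 and 1 adjusted over the list alone). The median was 0.44 (camera adjusted p = 0.00021, 0.036 with an estimated correlation, and on the deposited scale 4 rose, 9 fell and the median was −1.16), with Slc2a1, the glucose transporter, at 2.97 (SE 0.25). For cholesterol synthesis, 13 of 23 measured genes rose and 2 fell (13 and 2 adjusted over the list alone). The median was 0.82 (camera adjusted p = 2.4e-07, adjusted p = 0.12 with an estimated correlation, and on the deposited scale 3 rose, 13 fell and the median was −0.84), with Hsd17b7 at 4.19 (SE 0.21) and Sqle at 2.84 (SE 0.17). For milk fat globule and lipid synthesis, 16 of 29 measured genes rose and 6 fell (17 and 6 adjusted over the list alone). The median was 1.31 (camera adjusted p = 2.4e-07, adjusted p = 0.36 with an estimated correlation, and on the deposited scale 9 rose, 14 fell and the median was −0.58), with Xdh at 4.07 (SE 0.23) and the desaturase Fads2 at 4.34 (SE 0.28). For STAT5 and prolactin signalling, 9 of 13 measured genes rose and 1 fell (9 and 2 adjusted over the list alone). The median was 1.32 (camera adjusted p = 1.5e-05, adjusted p = 0.11 with an estimated correlation, and on the deposited scale 1 rose, 6 fell and the median was −0.60). Elf5, a transcription factor of secretory cells, rose by 4.71 (SE 0.28) and the prolactin receptor gene Prlr changed by −1.67 (SE 0.45).

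Organelle lists were the subject named in the title. For Golgi and secretory trafficking, 26 of 35 measured genes rose and 1 fell (27 and 1 adjusted over the list alone). The median was 0.72 (camera adjusted p = 4.7e-12, adjusted p = 0.24 with an estimated correlation, 0.51 on the deposited scale where 1 rose, 31 fell and the median was −1.19). For the endoplasmic reticulum unfolded protein response, 18 of 31 measured genes rose and 3 fell (19 and 4 adjusted over the list alone). The median was 0.52 (camera adjusted p = 1.1e-06, adjusted p = 0.28 with an estimated correlation, 0.16 on the deposited scale where 1 rose, 23 fell and the median was −1.30), with Fkbp11 at 5.39 (SE 0.25), Derl3 at 4.65 (SE 0.50) and the chaperone Hspa5 at 1.34 (SE 0.18), which on the deposited scale was −0.60. For the integrated stress response, 10 of 20 measured genes rose and 0 fell (10 and 1 adjusted over the list alone). The median was 0.66 (camera adjusted p = 8.1e-05, 0.036 with an estimated correlation, and on the deposited scale 0 rose, 10 fell and the median was −0.60), with Trib3 at 2.48 (SE 0.34), the asparagine synthetase Asns at 2.25 (SE 0.29) and the regulator Atf4 at 1.63 (SE 0.19, deposited scale −0.32). For the mitochondrial unfolded protein response, 3 of 25 measured genes rose and 2 fell (3 and 1 adjusted over the list alone). The median was 0.06 (camera adjusted p = 0.082, and on the deposited scale 0 rose, 22 fell and the median was −1.87). For the mitochondrially encoded transcripts, 0 of 13 measured genes rose and 2 fell (0 and 0 adjusted over the list alone). The median was −0.15 (camera adjusted p = 0.82, with the test pointing up). For fatty acid oxidation, 2 of 24 measured genes rose and 15 fell (2 and 15 adjusted over the list alone). The median was −0.68 (camera adjusted p = 0.042, adjusted p = 0.64 with an estimated correlation, 0.14 on the deposited scale), with Cpt1a, which admits fatty acids to mitochondria, at −2.67 (SE 0.23) and Decr1 at −2.74 (SE 0.33), while Ucp3 rose by 4.51 (SE 0.42).

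Tissue markers were tested next. Among white adipocyte markers, 1 of 21 measured genes rose and 18 fell (1 and 18 adjusted over the list alone). The median was −3.79 (camera adjusted p = 1e-07, adjusted p = 0.36 with an estimated correlation). The one that rose was Thrsp (1.81, SE 0.36, deposited scale −0.15). For collagens and extracellular matrix, 1 of 29 measured genes rose and 27 fell (1 and 27 adjusted over the list alone). The median was −2.84 (camera adjusted p = 1e-09, adjusted p = 0.36 with an estimated correlation), with Col1a1 at −3.17 (SE 0.35) and, in the other direction, Tnc at 3.87 (SE 0.27). For fibroblasts, 0 of 16 measured genes rose and 15 fell (0 and 15 adjusted over the list alone). The median was −2.99 (camera adjusted p = 3.7e-07, adjusted p = 0.33 with an estimated correlation). For hormone-sensing luminal epithelium, 0 of 11 measured genes rose and 9 fell (0 and 9 adjusted over the list alone). The median was −3.22 (camera adjusted p = 0.00037, adjusted p = 0.36 with an estimated correlation, 0.079 on the deposited scale). By limma, 350 of 16162 genes were higher and 14350 lower on day 8 on the deposited scale, where the median gene was at −1.81. On the non-milk scale 2136 were higher and 5101 lower with a median of −0.31, and 1074 of the genes called on both scales had opposite signs.

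C57 glands of days 14 and 21 also stood far from the non-lactating state. Against non-lactating glands Csn2 was at 8.07 (SE 0.38) on day 14 and 8.04 (SE 0.38) on day 21, Lalba at 7.56 and 7.55, Slc34a2 at 9.77 (SE 0.38) and 9.82 (SE 0.38), and Fabp3 at 9.25 and 9.26. Sncg was at −6.32 (SE 0.53) and −6.93 (SE 0.53), and Npr3 at −6.25 (SE 0.45) and −6.56 (SE 0.45). Among milk protein genes, on day 14, 17 of 19 measured genes rose and 1 fell (17 and 1 adjusted over the list alone). The median was 6.87 (camera adjusted p = 8.4e-85, 1.1e-06 with an estimated correlation). On day 21, 17 of 19 measured genes rose and 1 fell (17 and 1 adjusted over the list alone). The median was 6.88 (camera adjusted p = 3.3e-85, 1.1e-06 with an estimated correlation). For cholesterol synthesis, on day 14, 15 of 23 measured genes rose and 0 fell (16 and 0 adjusted over the list alone). The median was 1.09 (camera adjusted p = 3.7e-10, adjusted p = 0.058 with an estimated correlation, and on the deposited scale 5 rose, 10 fell and the median was −0.60). On day 21, 14 of 23 measured genes rose and 0 fell (14 and 0 adjusted over the list alone). The median was 0.92 (camera adjusted p = 1.3e-09, adjusted p = 0.07 with an estimated correlation, and on the deposited scale 5 rose, 11 fell and the median was −0.60). For white adipocytes, on day 21, 1 of 21 measured genes rose and 18 fell (1 and 18 adjusted over the list alone). The median was −3.63 (camera adjusted p = 3e-09, adjusted p = 0.34 with an estimated correlation). Deposited counts were 418 higher and 13944 lower on day 14 (median −1.59) and 405 and 13984 on day 21 (median −1.6). On the non-milk scale they were 2282 and 4023 on day 14 (median −0.19) and 2258 and 4189 on day 21 (median −0.2).

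NZB glands also switched to milk secretion by day 8. Csn2 rose by 5.84 (SE 0.38), Wap by 5.74 (SE 0.37), Lalba by 5.16 (SE 0.26) and Cel, a lipase secreted in milk, by 6.09 (SE 0.32). Slc34a2 rose by 7.66 (SE 0.38), Fabp3 by 7.46 (SE 0.30), Atp2b2 by 7.39 (SE 0.39), the mucin gene Muc1 by 6.83 (SE 0.27) and the folate receptor gene Folr1 by 6.67 (SE 0.37). Among the genes that fell were Dgat2 (−5.42, SE 0.55), Plin1 (−4.86, SE 0.43), Sncg (−5.35, SE 0.53), the adrenergic receptor gene Adrb3 (−4.69, SE 0.44), Aoc3 (−4.56, SE 0.36) and Slc1a5 (−4.65, SE 0.40).

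In the milk protein list, 18 of 19 measured genes rose and 1 fell (18 and 1 adjusted over the list alone). The median was 5.47 (camera adjusted p = 6.9e-81, 1.6e-06 with an estimated correlation). For calcium and ion transport, 11 of 15 measured genes rose and 2 fell (11 and 2 adjusted over the list alone). The median was 3.00 (camera adjusted p = 3.4e-09, 0.002 with an estimated correlation). For lactose synthesis and glucose transport, 8 of 13 measured genes rose and 1 fell (8 and 1 adjusted over the list alone). The median was 1.09 (camera adjusted p = 4.7e-05, 0.021 with an estimated correlation, and on the deposited scale 4 rose, 7 fell and the median was −0.64), with B4galt1 at 4.79 (SE 0.27) and the sugar transporter Slc5a1 at 5.17 (SE 0.29). For Golgi and secretory trafficking, 28 of 35 measured genes rose and 0 fell (29 and 0 adjusted over the list alone). The median was 0.93 (camera adjusted p = 3e-14, adjusted p = 0.16 with an estimated correlation, 0.1 on the deposited scale where 0 rose, 29 fell and the median was −0.98). For the endoplasmic reticulum unfolded protein response, 17 of 31 measured genes rose and 2 fell (19 and 2 adjusted over the list alone). The median was 0.62 (camera adjusted p = 1.6e-06, adjusted p = 0.29 with an estimated correlation, 0.15 on the deposited scale where 3 rose, 22 fell and the median was −1.25). For the integrated stress response, 6 of 20 measured genes rose and 0 fell (6 and 0 adjusted over the list alone). The median was 0.35 (camera adjusted p = 0.001, adjusted p = 0.093 with an estimated correlation, and on the deposited scale 3 rose, 13 fell and the median was −1.35), with Trib3 at 3.54 (SE 0.34) and Asns at 2.85 (SE 0.29). For fatty acid oxidation, 2 of 24 measured genes rose and 17 fell (2 and 19 adjusted over the list alone). The median was −0.96 (camera adjusted p = 0.0011, adjusted p = 0.44 with an estimated correlation). Of white adipocyte markers, 2 of 21 measured genes rose and 18 fell (2 and 18 adjusted over the list alone). The median was −3.79 (camera adjusted p = 5.4e-07, 0.44 with an estimated correlation). Luminal secretory markers rose in NZB: 11 of 17 measured genes rose and 2 fell (11 and 3 adjusted over the list alone). The median was 1.75 (camera adjusted p = 1.3e-06, adjusted p = 0.38 with an estimated correlation). B cell markers fell: 0 of 13 measured genes rose and 13 fell (0 and 13 adjusted over the list alone). The median was −3.48 (camera adjusted p = 0.0034, adjusted p = 0.76 with an estimated correlation, 0.94 on the deposited scale), with Blk at −3.48 (SE 0.77) and Ms4a1 at −3.40 (SE 0.78). This fall rested on NZB non-lactating mice 2 and 3, which were high in lymphocyte genes. Without them no gene of the list passed on the non-milk scale (median −0.46) and 5 fell on the deposited scale, with Blk at −0.46 (adjusted p = 0.6) and Ms4a1 at −0.74 (0.51). By limma, 481 genes were higher and 14319 lower on the deposited scale (median −1.8), and 2417 and 5263 on the non-milk scale (median −0.31).

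On day 14 NZB glands held Csn2 at 5.75 (SE 0.38) and Prol1 at 7.94 (SE 0.51) over the non-lactating level, with Plin1 at −4.50 (SE 0.43). The counts were 587 higher and 14148 lower (median −1.73), and on the non-milk scale 2542 and 4963 (median −0.33). On day 21, again over the non-lactating level, Prol1 stood at 9.58 (SE 0.51), lactoferrin (Ltf) at 8.38 (SE 0.58), the iron-sequestering lipocalin Lcn2 at 7.71 (SE 0.43), Slc5a8 at 8.03 (SE 0.88), Wfdc17 at 7.24 (SE 0.99), the connexin gene Gjb2 at 6.90 (SE 0.50) and the mucin gene Muc4 at 6.38 (SE 1.02). The B cell regulator Pax5 (−5.26, SE 1.22), Bank1 (−3.87, SE 0.83) and the fat cell genes Adrb3 (−3.41, SE 0.44) and Plin1 (−2.53, SE 0.43) were lower than in non-lactating glands. Without NZB non-lactating mice 2 and 3, which were high in lymphocyte genes, the calls of Pax5 (−1.07, adjusted p = 0.56) and Bank1 (−1.21, 0.34) ended.

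In the milk protein list, 18 of 19 measured genes rose and 1 fell (18 and 1 adjusted over the list alone). The median was 3.95 (camera adjusted p = 8.3e-31, 0.0008 with an estimated correlation). For involution and acute phase, a list of genes known to rise when milk removal stops, 13 of 24 measured genes rose and 0 fell (14 and 0 adjusted over the list alone). The median was 1.77 (camera adjusted p = 1.9e-07, adjusted p = 0.3 with an estimated correlation), with Lbp at 3.88 (SE 0.21). For involution cell death and proteases, 11 of 24 measured genes rose and 2 fell (14 and 2 adjusted over the list alone). The median was 0.74 (camera adjusted p = 0.0041, adjusted p = 0.2 with an estimated correlation), with the secreted chaperone Clu at 4.96 (SE 0.45) and Tgfb3, a growth factor of early involution, at 3.98 (SE 0.47). Without NZB non-lactating mice 2 and 3 the list had a median of 0.7 and did not pass (camera adjusted p = 0.094). For the lysosome, 22 of 43 measured genes rose and 1 fell (23 and 1 adjusted over the list alone). The median was 0.61 (camera adjusted p = 1.1e-05, adjusted p = 0.2 with an estimated correlation), with the protease Ctsl at 3.45 (SE 0.29) and the acid lipase Lipa at 3.23 (SE 0.20). For autophagy, 15 of 26 measured genes rose and 0 fell (16 and 0 adjusted over the list alone). The median was 0.65 (camera adjusted p = 0.0002, adjusted p = 0.22 with an estimated correlation), with Wipi1 at 2.14 (SE 0.18). For cytosolic heat shock, 12 of 17 measured genes rose and 0 fell (14 and 0 adjusted over the list alone). The median was 1.08 (camera adjusted p = 1.1e-05, adjusted p = 0.22 with an estimated correlation). For the tricarboxylic acid cycle, 1 of 20 measured genes rose and 11 fell (1 and 14 adjusted over the list alone). The median was −0.58 (camera adjusted p = 0.00012, adjusted p = 0.53 with an estimated correlation). By limma, 1590 genes were higher and 5139 lower on the deposited scale (median −0.4), and 2775 and 2527 on the non-milk scale (median −0.06). Muscle genes were high in NZB day 21 mice 1 and 2, and without them 2107 genes were higher and 1839 lower on the non-milk scale.

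The lactation changes of C57 and NZB used separate non-lactating controls, so their overlap could be counted. On the deposited scale 293 genes were higher on day 8 in both genotypes, against 10 for independent lists, and 13757 were lower in both, against 12714. On day 14 the counts were 331 (15) and 13339 (12206), and on day 21 298 (40) and 4852 (4446), where 9 genes higher in C57 were lower in NZB and 728 went the opposite way. On the non-milk scale 1751 genes were higher on day 8 in both genotypes, against 320 for independent lists, and 3767 were lower in both, against 1663. On day 14 the counts were 1791 (359) and 3024 (1237). On day 21 they were 1308 (388) and 1598 (656), and 42 genes higher in C57 were lower in NZB while 219 went the opposite way.

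The steps between lactation days were tested within each genotype. From day 8 to day 14 in C57, Wfdc2 rose by 5.18 (SE 0.77), the metallothionein gene Mt2 by 4.75 (SE 0.84), the chloride channel regulators Clca3a2 and Clca2 by 4.10 (SE 0.80) and 3.28 (SE 0.45), the growth factor gene Tgfb2 by 3.16 (SE 0.57) and Prol1 by 3.42 (SE 0.51). Genes that fell were Drd4, a dopamine receptor gene (−4.49, SE 0.48), Chrdl2 (−3.03, SE 0.37), the sialyltransferase gene St3gal4 (−2.64, SE 0.27), the protease gene Adamts5 (−2.55, SE 0.55) and osteopontin, Spp1 (−4.86, SE 0.97, deposited scale). In C57, 106 genes rose and 34 fell, and 241 and 111 on the non-milk scale. The count of 140 was 48 or 38 without C57 day 8 mouse 2 or 3, and 50 or 44 without C57 day 14 mouse 1 or 3. Adamts5 lost its call without C57 day 8 mouse 2 or 3 or C57 day 14 mouse 1 or 3 (adjusted p = 0.0539 to 0.114), Spp1 without C57 day 8 mouse 1 (0.0931) or C57 day 14 mouse 3 (0.0908), and Clca3a2 without C57 day 14 mouse 1 (0.0589). For complex I, 0 of 37 measured genes rose and 0 fell (0 and 0 adjusted over the list alone). The median was −0.34 (camera adjusted p = 3.8e-11, adjusted p = 0.62 with an estimated correlation). For the cytosolic ribosome, 0 of 60 measured genes rose and 0 fell (0 and 0 adjusted over the list alone). The median was −0.44 (camera adjusted p = 2.9e-21, 0.62 with an estimated correlation).

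Over the same days in NZB, Prol1 rose by 3.72 (SE 0.51), the sorting receptor gene Sorl1 by 1.75 (SE 0.25) and the milk fat globule gene Mfge8 by 1.26 (SE 0.24). Drd4 (−3.25, SE 0.48), Adamts5 (−2.85, SE 0.55), St3gal4 (−2.05, SE 0.27) and Pank3, of coenzyme A synthesis (−1.78, SE 0.31), fell. In all 7 genes rose and 17 fell (40 and 43 on the non-milk scale). The count of 24 was 11 or 3 without NZB day 8 mouse 1 or 2 and 7 without NZB day 14 mouse 1 or 3. It was 0 with the compared groups alone. Adamts5 lost its call without NZB day 8 mouse 2 or 3 or NZB day 14 mouse 1 or 3, Mfge8 without any of the 6 mice but NZB day 14 mouse 2, and Pank3 without NZB day 14 mouse 3 (adjusted p = 0.0567 to 0.221). For involution and acute phase, 1 of 24 measured genes rose and 0 fell (4 and 0 adjusted over the list alone). The median was 0.77 (camera adjusted p = 0.00018, adjusted p = 0.9 with an estimated correlation). In C57 the list moved the same way: 1 of 24 measured genes rose and 0 fell (7 and 0 adjusted over the list alone). The median was 0.75 (camera adjusted p = 0.018, adjusted p = 0.78 with an estimated correlation), and the difference in change did not pass (camera adjusted p = 0.48). The 2 genotypes did not differ in this step at any gene by limma, where 0 genes passed for the difference in change (347 at an unadjusted p under 0.05, 0 by limma voom), and 1 did without C57 day 14 mouse 1.

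From day 14 to day 21 the genotypes parted. In C57 no gene passed (limma, 0 genes, 19 at an unadjusted p under 0.05, and 0 by limma voom on recovered reads). Genes that fell in NZB were Slc34a2 (−6.34, SE 0.38), Atp2b2 (−6.00, SE 0.39), the chemokine gene Ccl28 (−4.37, SE 0.46), Gsdmc (−4.49, SE 0.43), Csn1s2a (−2.83, SE 0.34) and Olah, which ends fatty acid synthesis at medium chains in milk (−2.57, SE 0.29). Wfdc17 rose by 4.51 (SE 0.99), the tight junction gene Cldn1 by 4.36 (SE 0.97), Hmox1, which degrades haem, by 3.82 (SE 0.47), Anxa1 by 3.56 (SE 0.48) and Igfbp5, an involution gene, by 3.50 (SE 0.74). For cholesterol synthesis, 0 of 23 measured genes rose and 15 fell (0 and 18 adjusted over the list alone). The median was −0.87 (camera adjusted p = 1.2e-22, 0.0023 with an estimated correlation, and on the deposited scale 7 rose, 6 fell and the median was 0.25). For the integrated stress response, 1 of 20 measured genes rose and 6 fell (1 and 8 adjusted over the list alone). The median was −0.73 (camera adjusted p = 1.2e-05, 0.013 with an estimated correlation, and on the deposited scale 10 rose, 0 fell and the median was 0.66). For the interferon response, 15 of 28 measured genes rose and 1 fell (17 and 1 adjusted over the list alone). The median was 0.96 (camera adjusted p = 0.00062, adjusted p = 0.56 with an estimated correlation, 0.11 on the deposited scale), with Gbp2 at 2.33 (SE 0.41). For complexes II to V, 0 of 40 measured genes rose and 12 fell (0 and 13 adjusted over the list alone). The median was −0.40 (camera adjusted p = 1.8e-11, adjusted p = 0.27 with an estimated correlation, 0.23 on the deposited scale where 31 rose, 0 fell and the median was 0.93). On the deposited scale 13867 genes rose and 148 fell with a median of 1.36, and on the non-milk scale 2622 and 977 with a median of 0.28. The balance depended on scaling, since 1392 rose and 4031 fell with median centring, and 1253 and 1503 with quantile normalization. Without NZB day 21 mice 1 and 2, which were high in muscle genes, 688 rose and 429 fell on the non-milk scale.

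The test of that difference in change, NZB less C57, was positive for Cldn1 (4.69, SE 1.37), Muc4 (5.13, SE 1.44), Anxa1 (4.11, SE 0.68), Hmox1 (3.86, SE 0.66), Igfbp5 (3.83, SE 1.04) and Ltf (3.81, SE 0.82). It was negative for Slc34a2 (−6.39, SE 0.54), Atp2b2 (−6.02, SE 0.56), Ccl28 (−4.38, SE 0.65), Pthlh, a calcium-regulating hormone of the lactating gland (−4.04, SE 0.48), and Olah (−2.60, SE 0.42). Of the milk proteins, 3 of 19 measured genes had a positive and 11 a negative difference (2 and 11 adjusted over the list alone). The median was −1.23 (camera adjusted p = 6.1e-36, 0.00032 with an estimated correlation). For cholesterol synthesis, 0 of 23 measured genes had a positive and 10 a negative difference (0 and 10 adjusted over the list alone). The median was −0.90 (camera adjusted p = 1.1e-20, 0.0036 with an estimated correlation, and on the deposited scale 4 were positive, 2 negative and the median was 0.29). For calcium and ion transport, 0 of 15 measured genes had a positive and 5 a negative difference (0 and 8 adjusted over the list alone). The median was −0.80 (camera adjusted p = 1.7e-09, 0.0022 with an estimated correlation, and on the deposited scale 5 were positive, 3 negative and the median was 0.64). For lactose synthesis and glucose transport, 0 of 13 measured genes had a positive and 4 a negative difference (0 and 5 adjusted over the list alone). The median was −0.61 (camera adjusted p = 5.1e-06, 0.0048 with an estimated correlation, and on the deposited scale 6 were positive, 1 negative and the median was 0.51). For cytosolic heat shock, 6 of 17 measured genes had a positive and 0 a negative difference (11 and 0 adjusted over the list alone). The median was 1.19 (camera adjusted p = 3.9e-06, adjusted p = 0.22 with an estimated correlation). In total 12040 genes had a positive and 85 a negative difference on the deposited scale (median 1.38), and 647 and 390 on the non-milk scale (median 0.29). With median centring 399 were positive and 1808 negative, and 265 and 557 with quantile normalization. For skeletal muscle, 2 of 19 measured genes had a positive and 0 a negative difference (3 and 0 adjusted over the list alone). The median was 2.74 (camera adjusted p = 0.00022, adjusted p = 0.58 with an estimated correlation, 0.79 on the deposited scale and the other way), and without NZB day 21 mice 1 and 2 the median was −0.1 on that scale (camera adjusted p = 0.68). Without these mice 232 genes had a positive and 185 a negative difference on the non-milk scale. The calls of Cldn1, Igfbp5 and Muc4 each ended without most single mice, at adjusted p = 0.0501 to 0.133, and without both of these (0.136 to 0.269).

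In non-lactating glands NZB and C57 were compared to ask what the genotypes differ in before lactation. Genes of the ductal epithelium were lower in NZB, among them Krt5 of basal cells (−3.24, SE 0.46), the luminal keratin Krt19 (−3.13, SE 0.60), Foxa1 (−2.98, SE 0.65), Epcam (−2.63, SE 0.38), Prlr (−2.84, SE 0.45), Pgr (−2.49, SE 0.63), the peptide transporter gene Slc15a2 (−3.36, SE 0.36), Chil1 (−3.18, SE 0.70) and Muc16 (−3.05, SE 0.77). The expressed sequence BB114814 was lower by 4.64 (SE 0.37). Lymphocyte genes were higher in NZB, among them Cd79a and Cd79b of the B cell receptor (4.01, SE 0.91 and 3.32, SE 0.80), the homing receptors Ccr7 (3.63, SE 1.04) and Cxcr5 (3.54, SE 0.86), Siglecg (3.60, SE 0.90), and Lck, Cd6 and Cd2 of T cells (3.58, SE 0.97, 3.32, SE 0.87 and 3.30, SE 0.86). The muscle gene Ttn was higher by 4.74 (SE 1.24). Csn2 (2.20, SE 0.38), Wap (2.21, SE 0.37) and Glycam1 (2.93, SE 0.43) were higher in NZB and Ltf lower (−2.39, SE 0.58).

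The NZB non-lactating glands differed among themselves. The T cell gene Cd3e stood at 2.16, 33.1 and 262 CPM in NZB mice 1, 2 and 3, the muscle gene Acta1 at 16.2, 5 and 109 CPM, and Krt5 at 3.76, 9.69 and 0.756 CPM, against 36.9, 53.8 and 35.9 CPM of Krt5 in C57. Among B cell markers, 13 of 13 measured genes were higher in NZB and 0 lower (13 and 0 adjusted over the list alone). The median was 3.21 (camera adjusted p = 3.2e-11, adjusted p = 0.3 with an estimated correlation), and without NZB mice 2 and 3 none passed (median 0.19). Among T cell markers, 8 of 18 measured genes were higher in NZB and 0 lower (18 and 0 adjusted over the list alone). The median was 2.85 (camera adjusted p = 3.2e-11, adjusted p = 0.35 with an estimated correlation), and without those mice none passed (median 0.07). For luminal secretory epithelium, 0 of 17 measured genes were higher in NZB and 13 lower (0 and 15 adjusted over the list alone). The median was −1.88 (camera adjusted p = 3.8e-17, adjusted p = 0.11 with an estimated correlation), with a median of −2.02 without those mice. For basal and myoepithelium, 0 of 14 measured genes were higher in NZB and 10 lower (0 and 11 adjusted over the list alone). The median was −1.58 (camera adjusted p = 1.3e-14, adjusted p = 0.11 with an estimated correlation). For hormone-sensing luminal epithelium, 0 of 11 measured genes were higher in NZB and 5 lower (0 and 7 adjusted over the list alone). The median was −1.34 (camera adjusted p = 4.4e-09, adjusted p = 0.13 with an estimated correlation). For the estrogen and progesterone response, 0 of 13 measured genes were higher in NZB and 6 lower (0 and 8 adjusted over the list alone). The median was −1.27 (camera adjusted p = 1.2e-08, adjusted p = 0.11 with an estimated correlation). For milk proteins, 12 of 19 measured genes were higher in NZB and 1 lower (13 and 1 adjusted over the list alone). The median was 1.54 (camera adjusted p = 1e-09, adjusted p = 0.15 with an estimated correlation). For skeletal muscle, 1 of 19 measured genes were higher in NZB and 0 lower (8 and 0 adjusted over the list alone). The median was 1.77 (camera adjusted p = 1.3e-05, adjusted p = 0.48 with an estimated correlation). By limma, 482 of 16162 genes were higher and 718 lower in NZB on the deposited scale, and 272 and 581 on the non-milk scale. The count of 1200 was 466 without NZB mouse 3, 641 without C57 mouse 2, 452 without NZB mice 2 and 3 and 2341 without NZB mouse 1. Without NZB mouse 3 the calls of Ttn, Foxa1, Pgr, Muc16, Ltf, mt-Nd3 and all 8 named lymphocyte genes ended (adjusted p = 0.0634 for Ltf to 0.339 for Ccr7). Without C57 mouse 2 the calls of 13 named genes ended (adjusted p up to 0.15), and without C57 mouse 1, C57 mouse 3 or NZB mouse 2 those of 9, 10 and 8, most of them lymphocyte genes. With the compared groups alone 6 genes passed, and with limma voom on recovered reads 530.

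**Figure D2:**
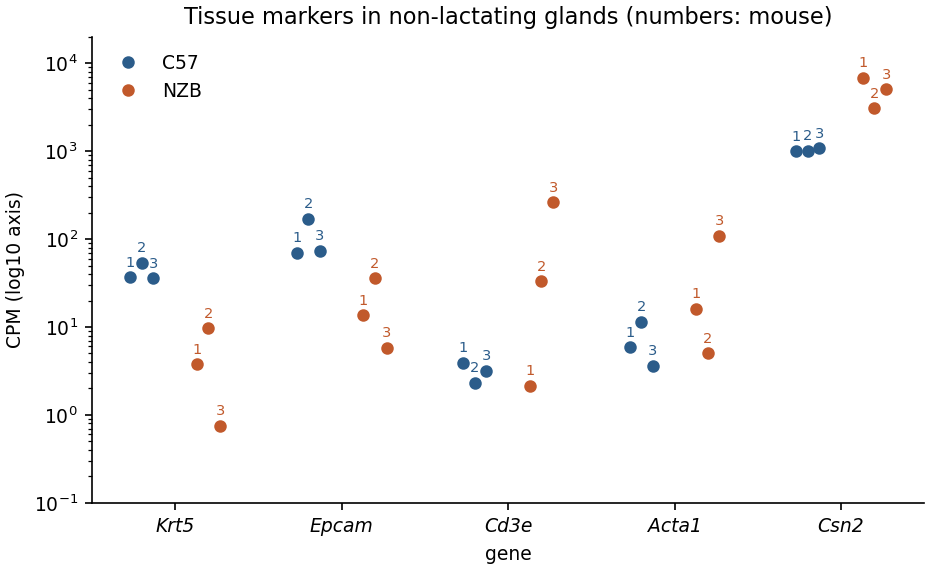
CPM of Krt5 and Epcam (epithelium), Cd3e (T cells), Acta1 (muscle) and Csn2 (milk) on a log10 axis in the 6 non-lactating glands, where each point is 1 mouse. Krt5 stood at 35.9 to 53.8 CPM in the C57 glands and 0.756 to 9.69 CPM in the NZB glands.

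On lactation days 8 and 14 few genes separated the genotypes. On day 8 Fam177a was higher in NZB by 1.67 (SE 0.23) and the other calls on the deposited scale were 4 copies of mitochondrial genes, Gm29216 at −10.66 (SE 0.29), Gm13340 at 7.06 (SE 0.23), Gm11410 at 6.76 (SE 0.29) and Gm13339 at 3.79 (SE 0.24). The pseudogene Gm4076 passed on the non-milk scale alone (1.48, SE 0.22). On day 14 the same 4 copies passed, at −10.50, 7.03, 6.79 and 3.74, and on the deposited scale mt-Nd3, a subunit of complex I, was at −1.76 (limma adjusted p = 0.026), where the non-milk scale gave −1.76 with an adjusted p of 0.12. Gm4076 (1.29, SE 0.22) and the immunoglobulin segment Igkv3-5 (3.29, SE 0.53) passed on the non-milk scale alone. Gm4076 lost this call without any 1 of the 6 mice but NZB mouse 2 (adjusted p = 0.0903 to 0.285), and Igkv3-5 without C57 mouse 1 or 3 or NZB mouse 2 or 3 (0.054 to 0.092). Summed with its copy Gm28438, as a share of mitochondrial reads, mt-Nd3 turned from −1.27 to 0.22. The copies share stretches with mitochondrial genes, so reads of the 2 cannot be told apart with certainty. The copies, Gm4076 and Igkv3-5 were named after their values were seen. By limma, 4 genes were higher and 1 lower on day 8 (232 at an unadjusted p under 0.05) and 3 and 2 on day 14 (182 at an unadjusted p under 0.05). On the non-milk scale the counts were 5 and 1 on both days. In data simulated for day 8 limma called 87% of 100 genes changed 4-fold and 28% of 100 changed 2-fold. Changes of 2-fold were thus mostly below what 3 mice per group could show.

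On lactation day 21 NZB glands were compared with C57 glands. Lower in NZB were Slc34a2 (−6.51, SE 0.38), Atp2b2 (−6.49, SE 0.39), Ccl28 (−4.69, SE 0.46), Pthlh (−4.48, SE 0.34), Serpina3g (−4.76, SE 0.88), Gsdmc (−4.26, SE 0.43), Slc9a4, a sodium-proton exchanger gene (−4.21, SE 0.39), and Plpp4 (−4.30, SE 0.59). Higher in NZB were the monocarboxylate transporter gene Slc5a8 (5.79, SE 0.88), Wfdc17 (5.05, SE 0.99), Angptl4, which restrains lipoprotein lipase (4.92, SE 0.69), Cyp2b19 (4.83, SE 0.43), Cyp24a1, which degrades vitamin D (4.79, SE 1.17), Igfbp5 (4.77, SE 0.74), the small heat shock protein gene Cryab (4.63, SE 0.59), Basp1 (4.48, SE 0.87), Anxa1 (4.25, SE 0.48) and Hmox1 (3.89, SE 0.47). Among the milk proteins Lao1 was at −3.54 (SE 0.34), Olah at −3.12 (SE 0.29), Csn1s2a at −2.60 (SE 0.34) and Csn2 at −2.02 (SE 0.38), while Ltf (3.74, SE 0.58) and Spp1 (3.76, SE 0.97) were higher.

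Among milk and lipid lists, for milk proteins 4 of 19 measured genes were higher in NZB and 11 lower (4 and 11 adjusted over the list alone). The median was −1.14 (camera adjusted p = 1.2e-35, 0.00034 with an estimated correlation). For milk fat globule and lipid synthesis, 5 of 29 measured genes were higher in NZB and 18 lower (5 and 19 adjusted over the list alone). The median was −1.39 (camera adjusted p = 9.2e-15, 0.11 with an estimated correlation, deposited scale −0.03 with 9 higher and 7 lower), with Fabp3 at −3.30 (SE 0.30). For cholesterol synthesis, 0 of 23 measured genes were higher in NZB and 14 lower (0 and 19 adjusted over the list alone). The median was −1.06 (camera adjusted p = 3.3e-23, 0.0023 with an estimated correlation, and on the deposited scale 6 were higher, 6 lower and the median was 0.27), with Insig1 at −2.74 (SE 0.30) and Fdps at −2.41 (SE 0.22). For lactose synthesis and glucose transport, 0 of 13 measured genes were higher in NZB and 6 lower (1 and 6 adjusted over the list alone). The median was −0.42 (camera adjusted p = 5.9e-06, 0.0046 with an estimated correlation, and on the deposited scale 7 were higher, 2 lower and the median was 0.54), with B4galt1 at −2.54 (SE 0.27). For calcium and ion transport, 2 of 15 measured genes were higher in NZB and 8 lower (3 and 8 adjusted over the list alone). The median was −0.88 (camera adjusted p = 3.8e-08, 0.0023 with an estimated correlation, and on the deposited scale 6 were higher, 4 lower and the median was 0.50). For involution and acute phase, 8 of 24 measured genes were higher in NZB and 0 lower (9 and 0 adjusted over the list alone). The median was 0.58 (camera adjusted p = 0.049, adjusted p = 0.78 with an estimated correlation, 0.96 on the deposited scale), with the endotoxin receptor gene Cd14 at 3.76 (SE 0.72) and the cytokine receptor gene Osmr at 2.59 (SE 0.34). For involution cell death and proteases, 9 of 24 measured genes were higher in NZB and 0 lower (12 and 0 adjusted over the list alone). The median was 0.67 (camera adjusted p = 0.049, adjusted p = 0.3 with an estimated correlation, 0.064 on the deposited scale), with Tgfb3 at 2.69 (SE 0.47), Mmp3 at 2.47 (SE 0.47) and Ctsl at 2.54 (SE 0.29).

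Among the organelle lists, for Golgi and secretory trafficking 0 of 35 measured genes were higher in NZB and 18 lower (0 and 22 adjusted over the list alone). The median was −0.49 (camera adjusted p = 1.4e-14, adjusted p = 0.16 with an estimated correlation, 0.67 on the deposited scale where 31 were higher, 0 lower and the median was 0.82). For the endoplasmic reticulum unfolded protein response, 2 of 31 measured genes were higher in NZB and 9 lower (2 and 11 adjusted over the list alone). The median was −0.23 (camera adjusted p = 5.9e-06, adjusted p = 0.3 with an estimated correlation, 0.67 on the deposited scale where 25 were higher, 0 lower and the median was 1.08), with P4hb, which forms disulfide bonds, at −1.73 (SE 0.19) and Hspa5 at −0.84 (SE 0.18), where the deposited scale gave 0.54. For cytosolic heat shock, 14 of 17 measured genes were higher in NZB and 0 lower (15 and 0 adjusted over the list alone). The median was 1.30 (camera adjusted p = 1.2e-06, adjusted p = 0.16 with an estimated correlation), with Hsp90aa1 at 1.93 (SE 0.27) and Hspa8 at 1.45 (SE 0.20). For fatty acid oxidation, 14 of 24 measured genes were higher in NZB and 0 lower (18 and 0 adjusted over the list alone). The median was 0.78 (camera adjusted p = 7e-05, adjusted p = 0.3 with an estimated correlation), with Cpt1a at 3.11 (SE 0.23). For antioxidant defence, 13 of 30 measured genes were higher in NZB and 2 lower (16 and 2 adjusted over the list alone). The median was 0.76 (camera adjusted p = 0.036, adjusted p = 0.66 with an estimated correlation, 0.054 on the deposited scale), and Sod2, the superoxide dismutase of mitochondria, was at −0.54 (SE 0.19, deposited scale 0.83). For the mitochondrial unfolded protein response, 1 of 25 measured genes were higher in NZB and 1 lower (0 and 1 adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.27, with the test pointing down), with Clpx at −1.26 (SE 0.16, deposited scale 0.13). Hspd1 (0.49), Hspa9 (0.25), Clpp (0.11), Lonp1 (−0.05), Atf5 (−0.07), Ddit3 (0.23), Sirt3 (−0.21) and Foxo3 (−0.04) did not pass on the non-milk scale, while on the deposited scale each was higher in NZB by 0.97 (Sirt3) to 1.76 (Hspd1). For the lysosome, 16 of 43 measured genes were higher in NZB and 5 lower (20 and 5 adjusted over the list alone). The median was 0.37 (camera adjusted p = 0.3).

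Cell markers were tested as well. For skeletal muscle, 18 of 19 measured genes were higher in NZB and 0 lower (19 and 0 adjusted over the list alone). The median was 2.87 (camera adjusted p = 2.7e-05, adjusted p = 0.53 with an estimated correlation, 0.96 on the deposited scale and the other way), with Acta1 at 57.6, 192 and 0.792 CPM in NZB mice 1, 2 and 3. For white adipocytes, 14 of 21 measured genes were higher in NZB and 3 lower (15 and 3 adjusted over the list alone). The median was 1.57 (camera adjusted p = 0.017, adjusted p = 0.78 with an estimated correlation, 0.56 on the deposited scale), with Adipoq at 2.20 (SE 0.51). For fibroblasts, 10 of 16 measured genes were higher in NZB and 0 lower (13 and 0 adjusted over the list alone). The median was 1.22 (camera adjusted p = 0.0022, 0.53 with an estimated correlation, 0.14 on the deposited scale). For macrophages, 10 of 17 measured genes were higher in NZB and 0 lower (11 and 0 adjusted over the list alone). The median was 1.19 (camera adjusted p = 0.0022, 0.45 with an estimated correlation, 0.097 on the deposited scale), with Cd68 at 1.78 (SE 0.37). For luminal secretory epithelium, 10 of 17 measured genes were higher in NZB and 2 lower (10 and 3 adjusted over the list alone). The median was 1.53 (camera adjusted p = 0.24), with Krt19 at 2.60 (SE 0.60). For collagens and extracellular matrix, 21 of 29 measured genes were higher in NZB and 1 lower (22 and 1 adjusted over the list alone). The median was 1.15 (camera adjusted p = 0.00012, 0.64 with an estimated correlation), with Col1a1 at 1.14 (SE 0.35). By limma, 13774 genes were higher and 162 lower in NZB on the deposited scale with a median of 1.35, and 3094 and 946 on the non-milk scale with a median of 0.3. With median centring 1436 were higher and 4223 lower, and 1427 and 1633 with quantile normalization. Of the genes called on both scales, 242 of 3487 had opposite signs. Without NZB mice 1 and 2, which held the muscle genes, 1041 genes were higher and 446 lower on the non-milk scale, in a fit where the lone NZB mouse was assumed to vary like the other groups. In that fit 14 of the genes named here and below for this comparison lost their call (adjusted p = 0.0507 to 0.341), among them Adipoq, Cd68, Krt19, Col1a1 and Sod2, and the lists of skeletal muscle (camera adjusted p = 0.98) and white adipocytes (0.22) did not pass. Sod2 lost its call without any 1 of 5 mice (all but C57 mouse 1, adjusted p = 0.0688 to 0.146), and Col1a1 without C57 mouse 3 or NZB mouse 1 or 3 (0.0566 to 0.115).

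**Figure D3:**
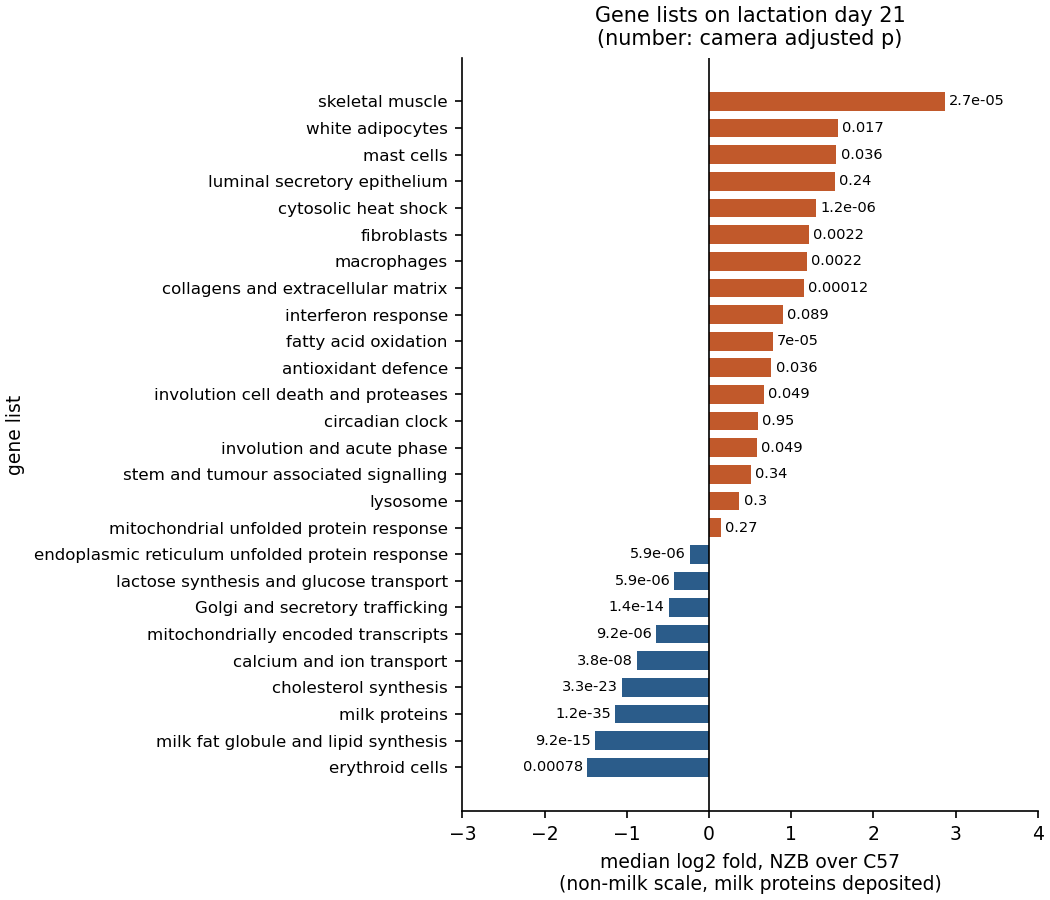
Median log2 fold (NZB over C57, non-milk scale; milk proteins on the deposited scale) of each named list on lactation day 21, with the camera adjusted p beside each bar. The medians run from −1.48 for erythroid cells to 2.87 for skeletal muscle.

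The change from the non-lactating state to day 8 was compared between genotypes. It holds the non-lactating difference with its sign reversed. With few genes apart on day 8, overlap of opposite sign was largely built in, for genes and lists. It was seen in 121 of 123 genes (deposited scale) and 111 of 121 (non-milk scale). The difference (NZB less C57) was positive for BB114814 (4.84, SE 0.52), Slc15a2 (3.93, SE 0.52), Krt5 (3.05, SE 0.65), Cdh1, of epithelial junctions (3.13, SE 0.64), Prlr (3.00, SE 0.63) and Epcam (2.73, SE 0.54). It was negative for Glycam1 (−2.90, SE 0.60), Wap (−2.26, SE 0.52), Lalba (−1.78, SE 0.37) and Fabp3 (−2.36, SE 0.43). Of the milk proteins, 0 of 19 measured genes had a positive and 5 a negative difference (1 and 12 adjusted over the list alone). The median was −1.32 (camera adjusted p = 1.1e-10, 0.15 with an estimated correlation). For luminal secretory epithelium, 2 of 17 measured genes had a positive and 0 a negative difference (14 and 0 adjusted over the list alone). The median was 1.69 (camera adjusted p = 1.6e-12, 0.21 with an estimated correlation). By limma, 105 genes had a positive and 18 a negative difference on the deposited scale, and 113 and 8 on the non-milk scale. The count of 123 was 783, 367 or 66 without NZB non-lactating mouse 1, 2 or 3, and 79 without C57 non-lactating mouse 2. Without C57 day 8 mouse 1, 2 or 3 it was 61, 23 or 35. Without NZB day 8 mouse 1, 2 or 3 it was 50, 31 or 40. The calls of Wap, Prlr, Krt5, Cdh1, Glycam1, Lalba, Epcam and Fabp3 each ended without at least 1 mouse, 8 of them without C57 day 8 mouse 2 (adjusted p = 0.0528 to 0.129). With limma voom 25 genes passed, and with the compared groups alone 16.

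Transcripts of mitochondrial DNA were compared because the genotype names point to it. The 13 protein-coding genes held 12.55% ± 1.98 (SD, n = 3) of the counts in C57 and 8.62% ± 2.66 in NZB non-lactating glands, 2.74% ± 0.28 and 2.83% ± 0.33 on day 8, 3.13% ± 0.43 and 2.14% ± 0.29 on day 14, and 3.23% ± 0.82 and 5.35% ± 1.1 on day 21. Over all 4 stages the mean was 4.73% in NZB and 5.41% in C57, a difference of −0.68 points (2-sided permutation p = 0.3791). With the milk protein genes left out of the total the means were 8.64% and 11.38%, a difference of −2.73 points (permutation p = 0.0025), and on that total the stages differed by −3.87, 0.23, −3.28 and −4.02 points in order (exact permutation p = 0.1, 0.8, 0.2 and 0.1). On all counts the difference without day 21 was −1.61 points (permutation p = 0.0071). Among single genes mt-Nd3 was lower in NZB before lactation (−1.49, SE 0.36) and on day 21 (−1.66, SE 0.36), and mt-Co2 on day 21 (−1.26, SE 0.26), where the deposited scale gave 0.13. As shares of mitochondrial and copy reads, which hide a difference in total, these differences did not hold with copies added. There mt-Nd3 went from −0.93 to 0.67 before lactation and −1.0 to −0.04 on day 21, where mt-Co2 went from −0.55 to −0.04. For the whole list on day 21, 0 of 13 measured genes were higher in NZB and 3 lower (0 and 3 adjusted over the list alone). The median was −0.64 (camera adjusted p = 9.2e-06, 0.41 with an estimated correlation). On the deposited scale 10 were higher, 0 lower and the median was 0.75.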

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

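The explanations tested here and the counts of other splits were chosen after the results were seen, and both comparisons of change between genotypes before. SE here is over the genes of a list, not mice.

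From lactation day 14 to day 21 the change differed between NZB and C57 in 12125 genes on the deposited scale (12040 positive, 85 negative). Of 100 splits of the 12 samples 6 gave as many genes, the real one included, with 13113 as the highest other, so chance cannot be excluded on this count. The 5 others kept NZB and C57 apart on day 21 alone, so the count rests on that grouping and says little about day 14. The non-milk scale gave 1037, and median centring 2207, mostly negative. From the non-lactating state to day 8 the change differed in 123 genes (105 positive, 18 negative). Here 3 of 100 splits gave as many, with 185 as the highest other, a share under 0.05. Both others kept the genotypes apart before lactation and mixed the glands of day 8, so this count rests on the non-lactating glands. There chance stays open, as another split gave 1161 genes against 1200. The 123 were 23 to 783 without 1 mouse, 25 with limma voom and 16 with the compared groups alone. From day 8 to day 14 limma called 0 genes (347 at an unadjusted p under 0.05, and 0 by limma voom), so splits, which cannot give fewer, decide nothing (highest other 4).

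On day 21 most genes had a higher CPM in NZB, and many differed outside the milk protein genes. A few milk protein genes taking most of the counts accounts for the general rise, since the median log2 fold of all genes went from 1.35 to 0.3 without them, but 4040 genes passed there, which argues against it for the rest. A lower share of epithelium in the NZB pieces stays open. Luminal, basal and hormone-sensing medians were 1.53 (SE 0.37), 0.81 (SE 0.14) and 0.66 (SE 0.35), and fibroblasts 1.22 (SE 0.18). Without NZB mice 1 and 2 they were 1.08, 0.21, −0.07 and 1.19. Skeletal muscle in 2 of the 3 NZB libraries is argued against as the whole cause, since 1487 genes passed without them while the muscle median went to 0.15 (SE 0.17). The genotype, and whether pups still nursed on day 21, which the labels do not give, also stay open, not tested apart.

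Before lactation NZB glands had higher B cell and T cell genes, lower epithelial genes and higher milk protein genes than C57. The lymphocyte genes rested on 2 of the 3 NZB libraries, without which the median of the B cell markers went from 3.21 (SE 0.2) to 0.19 (SE 0.06). These libraries were singled out by such genes, so their removal does not show the source, and lymph node tissue stays open. A lower share of epithelium in the NZB pieces could account for the epithelial genes, with luminal markers at −1.88 (SE 0.21), basal markers at −1.58 (SE 0.27) and hormone-sensing markers at −1.34 (SE 0.29), but is argued against for the milk protein genes, whose median was 1.54 (SE 0.31). Reads carried over from lactating libraries of both genotypes are argued against, since at least 38.3 reads of Gm29216 would be called for in each NZB library and 0 were found. A few secreting lobules, carry-over from NZB lactating libraries alone and the genotype stay open and were not tested.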

How the results depend on the processing

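The settings named as added below were chosen after the data were seen: pseudocount 0.1, the first or second columns alone, limma voom on recovered reads, removals of 2 or 3 libraries, the shares without day 21 or with nuclear copies, and the deposited scale set beside gene and list values. The planned edgeR and DESeq2 tests were not run, since the deposited unit is not a count, and the planned pseudocount of 1 is the value already used. The first column of C57 non-lactating mouse 2 held 2174916 reads, and with the first or the second columns alone all 17 counts of genes stayed within 1.5 times, so no limit set by its depth was seen in them. Fits that leave a group with 1 sample assume that the lone sample varies like the other groups. The cause of a change was not tested unless a sentence names it.

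Counts of genes moved by over 1.5 times most under scaling. With median centring NZB and C57 differed on day 21 in 5659 genes (1436 higher, 4223 lower), lactation in C57 in 8947, 8181 and 8353 genes on days 8, 14 and 21 and in NZB in 8933 and 8284 on days 8 and 14. The steps from day 8 to day 14 gave 243 (C57) and 63 (NZB), the step to day 21 in NZB 5423 (1392 rose, 4031 fell), and the differences in change 190 to day 8 and 2207 to day 21 (399 positive, 1808 negative). Without the milk protein genes the same results, in order, were 4040, then 7237, 6305 and 6447, 7680 and 7505, 352 and 83, 3599, and 1037 to day 21. With quantile normalization they were 3060 (1427 higher, 1633 lower), then 6886, 6215 and 6341, 7193 and 6837, 305 and 89, 2756 (1253 rose, 1503 fell), and 822 (265 positive, 557 negative) to day 21. Scaling acts on all genes of a sample at once.

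With no filter the steps to day 14 gave 88 (C57) and 11 (NZB), where more genes were tested. With the compared groups alone, which leaves fewer samples to estimate spread, the counts were 6 for the genotypes before lactation, 10 on day 8, 3651 for lactation day 21 in NZB, 0 for the step to day 14 in NZB (1109 at an unadjusted p under 0.05 with all samples) and 16 for the difference in change to day 8. Pseudocount 0.1 gave 629 and limma voom 530 for the genotypes before lactation, and 71 and 25 for the difference in change to day 8.

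Without NZB non-lactating mice 2 and 3, counts were 452 for the genotypes before lactation and 3840 for lactation day 21 in NZB, and 333 and 4123 when C57 non-lactating mouse 2 was left out too. Without the milk protein genes and those 2 NZB mice the genotypes differed in 295 genes, and lactation in NZB in 5256, 4795 and 4265 on days 8, 14 and 21. Without the milk protein genes, C57 day 14 mouse 1 and NZB day 14 mouse 3, counts were 5889 and 6368 for lactation day 14 in C57 and NZB, 3122 for the step to day 21 in NZB, and 1 and 856 for the differences in change to days 14 and 21. Without the milk protein genes and NZB day 21 mice 1 and 2 the genotypes differed on day 21 in 1487 genes, lactation day 21 in NZB in 3946, the step to day 21 in NZB in 1117 and its difference in change in 417.

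Leaving out 1 mouse at a time gave 466 to 2341 genes for the genotypes before lactation, 23 to 783 for the difference in change to day 8, 38 to 199 and 3 to 31 for the steps to day 14 in C57 and NZB, and 0 to 1 for the difference in change to day 14. The milk protein share differed by −17.32 to −10.15 points and the mitochondrial by −1.18 to 0.16, as uneven stages shift pooled means. Without day 21 they differed by 0.53, where the sign turned, and −1.61. The second differed by −2.73 with milk protein genes out of the total.

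On the deposited scale the folds of these genes took the other sign: on day 21 Hspa5 0.54, Sod2 0.83, Clpx 0.13, mt-Co2 0.13, Lonp1 1.24, Atf5 1.2, Sirt3 0.97 and Foxo3 1.35, and for day 8 in C57 Hspa5 −0.6, Atf4 −0.32, Thrsp −0.15 and Arntl −0.05. Among lists the skeletal muscle call of day 21 ended with the direction turned (camera adjusted p = 0.96), and with quantile normalization the mitochondrially encoded transcripts of C57 day 8 passed as lower (camera adjusted p = 2.3e-05). For skeletal muscle the difference in change to day 21 also ended with the direction turned, on the deposited scale (camera adjusted p = 0.79) and without NZB day 21 mice 1 and 2 (0.68). Without these 2 mice 19 values of named genes lost the call, where a gene named in several comparisons counts in each. For named genes 4470 of the values under alternatives kept direction and call, 345 kept the direction and lost the call, 8 gained one and 12 turned. For lists the numbers were 580, 99, 15 and 4.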

Other observations

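The tests of nuclear copies, the count of neighbouring genes and the counts of other splits in this part were chosen after the results were seen, and the gene lists before.

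Clock genes moved in opposite directions, and the hour of collection was not tested. In C57 on day 8 against non-lactating glands 5 of 16 measured clock genes rose and 8 fell (5 and 8 adjusted over the list alone). The median was −1.11 (camera adjusted p = 0.61). The output genes Dbp (−4.26, SE 0.42) and Per3 (−2.66, SE 0.25) fell while Arntl, which drives them, rose by 1.83 (SE 0.35, deposited scale −0.05). On day 21, NZB against C57, 6 of 16 measured genes were higher in NZB and 4 lower (9 and 4 adjusted over the list alone). The median was 0.59 (camera adjusted p = 0.95), with Dbp at 2.45 (SE 0.42), Per3 at 1.44 (SE 0.25), Bhlhe41 at 3.70 (SE 0.60) and Arntl at −1.82 (SE 0.35). Endothelial markers fell in C57 on day 8: 1 of 16 measured genes rose and 11 fell (1 and 12 adjusted over the list alone). The median was −1.15 (camera adjusted p = 0.017, adjusted p = 0.64 with an estimated correlation, 0.2 on the deposited scale), with Pecam1 at −1.49 (SE 0.21), while Prox1, known from lymphatic endothelium, rose by 3.81 (SE 0.36). Among plasma cell genes on day 14 in C57, 8 of 11 measured genes rose and 2 fell (8 and 2 adjusted over the list alone). The median was 3.31 (camera adjusted p = 0.00015, 0.2 with an estimated correlation).

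On day 21, NZB against C57, 6 of 8 measured mast cell genes were higher and 0 lower (6 and 0 adjusted over the list alone). The median was 1.55 (camera adjusted p = 0.036, adjusted p = 0.4 with an estimated correlation, 0.73 on the deposited scale), with Kit at 2.90 (SE 0.67) and the chymase gene Cma1 at 2.27 (SE 0.44). For erythroid cells, 0 of 7 measured genes were higher in NZB and 4 lower (0 and 5 adjusted over the list alone). The median was −1.48 (camera adjusted p = 0.00078, 0.3 with an estimated correlation, deposited scale −0.1 with 2 higher and 0 lower), with Hbb-bt at −2.19 (SE 0.47). For the interferon response, 9 of 28 measured genes were higher in NZB and 2 lower (11 and 2 adjusted over the list alone). The median was 0.90 (camera adjusted p = 0.089), with Gbp2 at 2.14 (SE 0.41) and Oasl2 at 1.66 (SE 0.37). For stem and tumour associated signalling, 8 of 21 measured genes were higher in NZB and 1 lower (9 and 1 adjusted over the list alone). The median was 0.51 (camera adjusted p = 0.34), with Notch1 at 1.92 (SE 0.28) and Aldh1a1 at 1.81 (SE 0.44). Without NZB day 21 mice 1 and 2 the calls of Kit, Hbb-bt, Oasl2 and Aldh1a1 ended.

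Of 10 nuclear copies of mitochondrial genes 5 parted the 2 genotypes in every sample. Gm29216 (chromosome 1, 24615706 to 24616197, GRCm38, a copy of mt-Co1) held 267.9 to 3591.28 CPM in the 12 C57 glands and 0 in the 12 NZB glands, while Gm13340 (chromosome 2, 22588103 to 22589647, also a copy of mt-Co1) held 0.63 to 2.68 and 114.09 to 694.64 CPM. A different amount of mitochondrial transcripts is argued against, because on day 8 the same mitochondrial gene had copies at 6.34 and −8.69 on the deposited scale. Strain variants in mitochondrial DNA that move reads between a gene and its copies stay open. Of the 5 separated copies, those higher in NZB shared at most 53.7% of their 25-base words with the reference gene, and those lower at least 97.2%. Yet Gm28438, with 99.1%, was higher in NZB before lactation (0.85, SE 0.23, a call that ended without C57 mouse 1 or 3 or NZB mouse 1 or 2, adjusted p = 0.066 to 0.141), and Gm28439, Gm28661 and Gm10925, with 100%, were not separated, so sequence sharing does not decide it. Whether the reads of both genotypes come from mitochondrial DNA was not tested, and with 14 of 32 gene and stage pairs nearer to 0 after summing each gene with its copies, single mitochondrial genes remain uncertain.

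Srp54a, Fam177a, Srp54b and 1700047I17Rik2 lie side by side on chromosome 12 (55080262 to 55217168, GRCm38) and had higher means in NZB at all 4 stages, a set chosen after its values were seen. Of them Fam177a alone passed on day 8 and none on day 14. On the non-milk scale Srp54a was at 1.79, 1.91, 2.02 and 1.75 in order of stage, Fam177a at 1.25, 1.67, 1.09 and 1.63, Srp54b at 0.71, 0.93, 0.91 and 0.6, and 1700047I17Rik2 at 1.94, 1.4, 1.71 and 1.57. It was the 1 window of 4 neighbouring genes among 15428 in which all differed by over 0.5 one way at all stages, and 30 single genes did so, 27 of them higher in NZB. Whether Srp54a and Srp54b share reads was not tested.

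A comparison of 3 samples against 3 allows 10 splits, too few for a share under 0.05, so each count is set beside the highest of the other splits. For NZB against C57 the counts were 1200 before lactation (highest other 1161), 5 on day 8 (0), 5 on day 14 (0) and 13936 on day 21 (1), and in each 1 of the 10 splits, the real one, gave as many. The split that gave 1161 set C57 mice 1 and 3 with NZB mouse 1 against the rest. For lactation in C57 the counts were 14700, 14362 and 14389 (highest other 0 on each day), and in NZB 14800 (0), 14735 (188) and 6729 (325). For the steps the counts were 140 (0) and 24 (0) from day 8 to day 14 in C57 and NZB, and 14015 (1) from day 14 to day 21 in NZB. From day 14 to day 21 in C57 all 10 splits gave at least the 0 genes of the real one, and the split that set C57 day 14 mice 1 and 3 and day 21 mouse 1 against the rest called 2762, which points to a structure of the samples other than the day.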
